A study of Mus musculus with 5 samples.

How the data were processed

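RNA from sorted mouse KLS cells was extracted with Trizol as total RNA, labelled with biotin and hybridised to Affymetrix mouse arrays, per the labels' protocols. The deposited table holds 1 intensity value per probe set and array. The authors made the intensity values with RMA (robust multi-array average), per the submitters' processing notes; the RMA software and version are not given in the sources used here, nor is whether the excluded array was part of that normalization. RMA models background, sets the arrays to a common distribution of intensities and summarises the probes of a set. It therefore forces the arrays to similar distributions, so a shift of all transcripts in 1 group would not be seen, and it compresses differences of dim probe sets. The deposited values ran from 6.96 to 31249 and were treated as linear intensities, and log2 was taken here. All 5 columns of the table were matched to samples, and the number of columns of other samples was 0. For arrays no depth applies: the number of arrays limits the precision.

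Arrays were grouped by their titles into 2 control arrays (titled wild type) and 3 Rb family deficient arrays. Pairwise Pearson correlations across probe sets ran from 0.979 to 0.993 and no 2 arrays were identical. Probe sets were named through GEO's platform annotation: 34945 had 1 gene symbol, 932 had several and 9160 were not listed with a gene. No gene was named from a probe set with several symbols. No symbol needed updating through the gene identifiers. Of 464 distinct genes in the fixed lists, 429 matched a probe set with 1 symbol and 35 did not. Genomic coordinates are not given because no genome build is named for the array.

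The comparison was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided tests) on log2 values of all 5 arrays with no covariate, and p-values were adjusted by Benjamini-Hochberg over 45037 probe sets, leaving out 64 AFFX control probe sets. The threshold was an adjusted p under 0.05. Another fit of the same kind used 1 probe set per gene, that with the highest mean over the 5 arrays (18193 genes), and was used for the gene lists. The 26 gene lists were fixed before the data were examined, as were the test, the alternatives and the rule for named genes. Of these, 24 lists were tested with camera (preset correlation 0.01, lists of at least 5 measured genes), and with an estimated correlation and with fry as alternatives; the targeted genes and the sex-linked genes were described and not tested as sets. Camera asks whether the genes of a list rank differently from other genes. Fry's directional p asks whether a list's genes move, on balance, in a single direction, and does not compare the list with other genes. Counts "adjusted over the list alone" apply Benjamini-Hochberg to the members of 1 list.

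The text names the 3 targeted genes, in each direction the 10 genes with the largest difference among probe sets with 1 symbol that passed the threshold and whose groups of arrays did not overlap, up to 4 genes of each list with the smallest unadjusted p, and control probe sets of Gapdh and beta-actin. Cd3g, Itgam and the alpha-globin probe sets fall outside this rule and were chosen after their values were seen, as were the closing section's names outside it. RNA quality measures were compared with an exact permutation test over the 10 ways to split the 5 arrays, which cannot give a p under 0.1.

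Data were simulated with the real means of the 45037 probe sets, spreads drawn from the distribution that eBayes fitted, and independent noise. There, 200 probe sets were changed and 20 more were shifted by 1 log2 unit. Among the 200, the fit recovered 22.4% of changes of 1 log2 unit, 91.0% of changes of 2 and 98.5% of changes of 4. Of 155 calls, 7 were false. Correlation between genes was left out, so the setting was simpler than the real data. Alternatives tried were quantile normalization again, cyclic loess, median centring, leaving out dim probe sets or those ending in _x_at or _s_at, an intensity trend or a robust prior in eBayes, array weights, other thresholds (adjusted p under 0.1, or at least 1.5-fold), the replicate number as a block, each array left out in turn, the mean of all probe sets of a gene, and, chosen after seeing the data, the Xist level and the poly-A spike level as covariates.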

Results

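RNA levels were measured on Affymetrix mouse arrays in KLS cells (c-Kit+, lineage-negative, Sca-1+), the sorted fraction of mouse blood-forming cells that contains haematopoietic stem cells and multipotent progenitors. The deficient group had lost RB, p107 and p130, the 3 pocket proteins, which bind E2F transcription factors and restrain entry into the cell cycle. The control group, titled wild type by the study, carried intact Rb1 and Rbl2 and 1 intact copy of the p107 gene. Deletion was induced with Mx1-Cre, a recombinase under an interferon-responsive promoter, at 6 weeks of age, and cells were sorted 2 months later. The files hold 2 control and 3 deficient arrays. The study hybridised 6 and left out 1 for high background and anomalous control probe sets. Median intensities lay between 26.1 and 26.7 on the 5 arrays. The labels do not say whether each array came from a separate animal or pool, so p-values measure only the spread between these samples. That spread may be partly technical, but not wholly, since Xist and Eif2s3y set deficient 2 far apart from deficient 1 and 3. The small number of arrays limits the precision of every value. Levels are given as mean ± SD of log2 intensity over the 2 control or 3 deficient arrays, and differences as deficient minus control on the log2 scale.

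The 3 inactivated genes were compared first, to check the labels. Rbl1, which encodes p107, had the largest difference of the 3. Its brightest probe set (1424156_at) read 7.75 ± 0.83 in controls and 4.71 ± 0.45 in deficient cells, a difference of -3.04 (SE 0.40), with every deficient array below both control arrays. This just missed the threshold over all probe sets (limma, Benjamini-Hochberg adjusted p = 0.0513) and passed it in the fit with 1 probe set per gene (adjusted p = 0.0266). Another Rbl1 probe set (1425166_at) differed by -0.91 (SE 0.17, adjusted p = 0.0961), and the other 2 probe sets of the gene read below 4 on all arrays. Rb1 did not pass on its brighter probe set (1417850_at), with 8.74 ± 0.13 in controls and 8.39 ± 0.58 in deficient cells (difference -0.36, SE 0.33, adjusted p = 0.732). That difference ran from -0.63 without deficient 1 to -0.05 without deficient 2. Rbl2, which encodes p130, read 8.31 ± 0.44 and 7.84 ± 0.27 on its brighter probe set (1425981_a_at; difference -0.46, SE 0.24, adjusted p = 0.473), and ran from -0.77 without control 2 to -0.16 without control 1. The positions of the probes relative to the deleted parts of the genes are not given in the sources used here, and a probe outside a deleted part does not check the deletion.

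**Figure D1:**
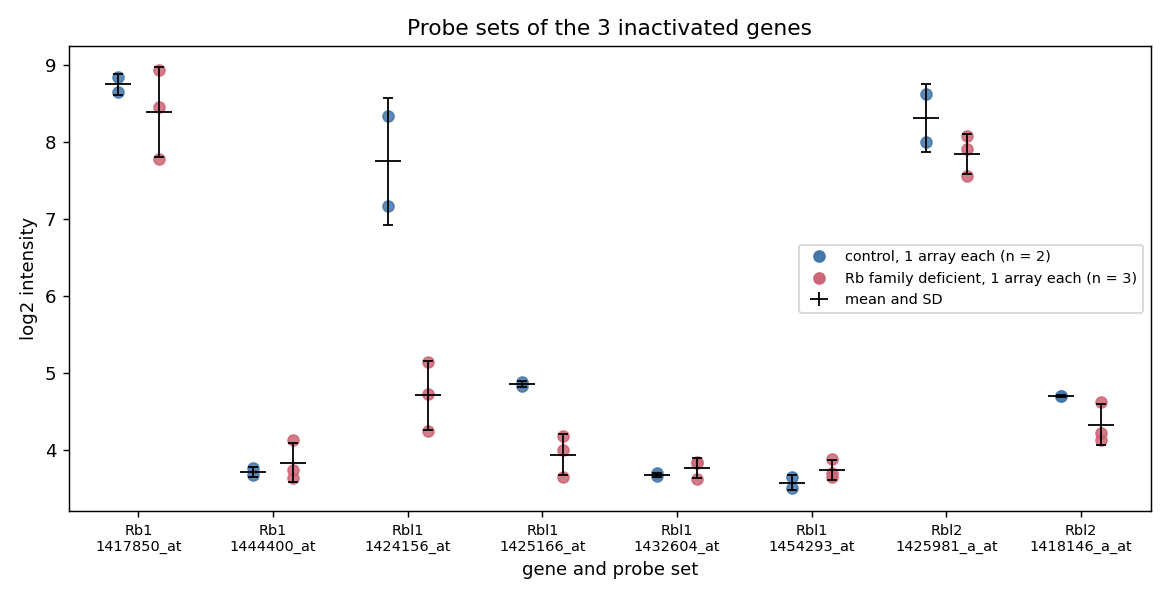
Log2 intensity of each probe set of Rb1, Rbl1 and Rbl2 on each control (n = 2) and Rb family deficient (n = 3) array, with the mean and SD in black. The groups are widest apart on the Rbl1 probe set 1424156_at, at 7.75 in controls and 4.71 in deficient cells.

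Immunoglobulin genes and neutrophil granule genes made up most of the 10 largest falls in the deficient arrays. Igha, the heavy chain of immunoglobulin A, fell from 13.04 ± 0.23 to 4.91 ± 0.16 (difference -8.12, SE 0.16, adjusted p = 0.000166). Jchain, which links immunoglobulin chains into polymers, fell by 7.48 on the log2 scale (SE 0.27) and the light-chain segment Igkv8-30 by 5.05 (SE 0.41). Among granule and neutrophil genes, the falls were 6.16 for Ngp (SE 0.31), 6.07 for the antimicrobial peptide gene Camp (SE 0.48), 5.81 for S100a9 (SE 0.36), 5.36 for Ltf, which encodes lactoferrin (SE 0.65), 5.30 for S100a8 (SE 0.43) and 4.93 for Cd177 (SE 0.34). The heat shock gene Hspa1b fell by 5.13 (SE 0.65). Those 10 genes had the largest falls among named genes past the threshold.

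Trnp1, a nuclear protein gene known from neural progenitors, had the largest rise, from 4.44 ± 0.24 to 8.54 ± 0.61 (difference 4.10, SE 0.35, adjusted p = 0.0183). The control levels of Trnp1 and Cenpe lay below the array medians of 4.71 to 4.74. The deficient levels of Igha, Jchain, Igkv8-30 and Cd177 lay close to or below those medians. RMA compresses differences there, so no fold is given and the log2 differences of these genes may be understated. The other 9 rises included genes of chromosome movement and separation: the kinetochore motor Cenpe rose by 1.84 (SE 0.20), the mitotic kinesin Kif20b by 1.75 (SE 0.12) and Espl1, the protease separase, by 1.61 (SE 0.13). Csf2rb, the shared receptor subunit for GM-CSF, IL-3 and IL-5, rose from 9.21 ± 0.17 to 10.90 ± 0.10 (1.69, SE 0.13). The RNA-binding protein gene Tia1 rose by 1.81 (SE 0.14), the transcription factor gene Zbtb16 by 1.74 (SE 0.21), the lipoprotein receptor gene Vldlr by 1.67 (SE 0.13), the histone methyltransferase gene Kmt2d by 1.66 (SE 0.17) and Tent5a by 1.65 (SE 0.17). The other probe set of Trnp1 differed by 0.02 and that of Kmt2d by -0.20, so those rises rest on 1 probe set each. Over all probe sets of a gene, the differences ranged from -0.25 to 1.81 for Tia1, from 0.15 to 1.75 for Kif20b and from 0.20 to 1.67 for Vldlr. Each of these 20 genes had adjusted p below 0.05 (limma) and groups of arrays that did not overlap.

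**Figure D2:**
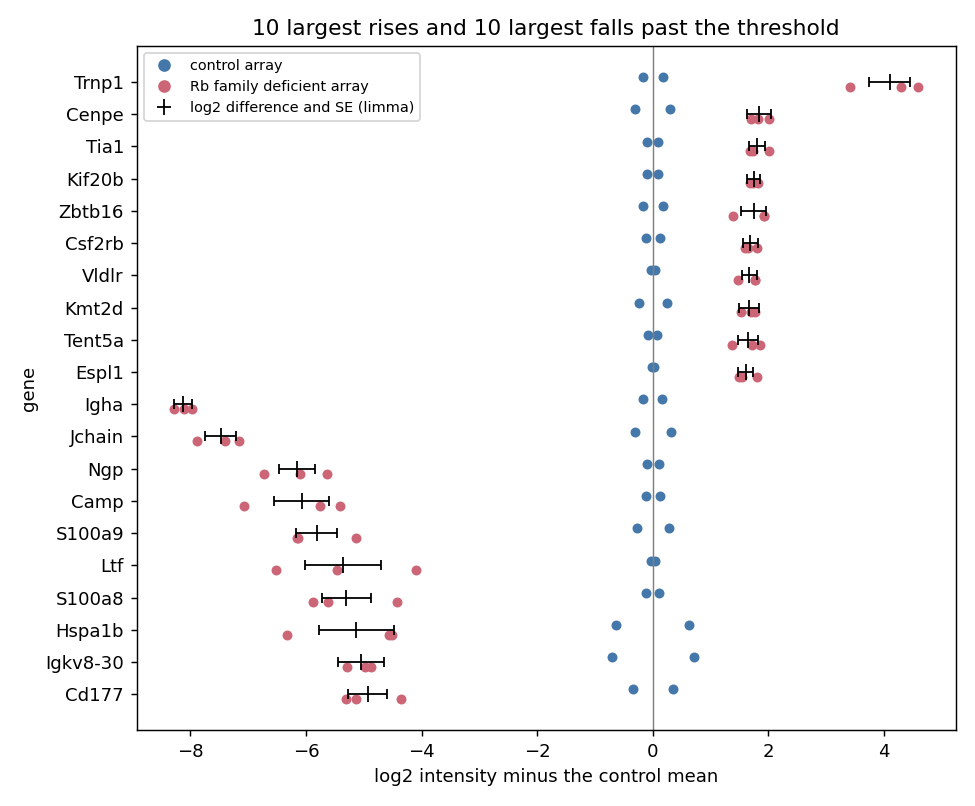
Log2 intensity minus the control mean for the 10 named genes with the largest rises and the 10 with the largest falls, with 1 point per array (2 control, 3 Rb family deficient) and the log2 difference and its SE in black. Falls reach -8.12 (Igha) and -7.48 (Jchain), while Trnp1, at 4.10, stands apart from the other rises, which lie between 1.61 and 1.84.

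Over all 45037 probe sets, 74 were higher and 147 lower in deficient cells at adjusted p under 0.05 (limma), against 3280 higher and 3071 lower at an unadjusted p under 0.05. With 1 probe set per gene, 151 of 18193 genes were higher and 257 lower. The 2 groups did not overlap on 13747 probe sets (30.5%), where chance gives 20%. The counts fell when any array was left out: 5 higher and 73 lower without control 1, 3 and 69 without control 2, 2 and 21 without deficient 1, 4 and 39 without deficient 2, and 3 and 27 without deficient 3. Of the 20 genes named above, Igha, Jchain and Ngp passed the threshold in all 5 of those fits, and 6 passed in none (Tia1, Zbtb16, Csf2rb, Kmt2d, Tent5a and Hspa1b), with every value keeping its direction. A gene that passed in none could still be steady in size, as was Csf2rb, whose difference ran from 1.565 to 1.807 with 1 array left out. Among the called probe sets, 8 carry several gene symbols and are not assigned to a gene. Among measures of RNA quality, the 3' minus 5' log2 signal was 4.64 ± 0.10 against 4.66 ± 0.21 for Gapdh (exact permutation test, two-sided p = 0.9) and 3.14 ± 0.03 against 3.42 ± 0.10 for beta-actin, and 18S ribosomal RNA read 10.92 ± 0.01 in controls and 10.23 ± 0.15 in deficient cells (exact permutation p = 0.1 for the last 2, the smallest that 2 against 3 arrays allow).

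Gene groups fixed beforehand were then compared, with camera, limma's competitive set test, on 24 lists. Camera called 6 lists higher and 7 lower with a preset correlation of 0.01 between genes. With an estimated correlation it called 0 lists (smallest adjusted p = 0.183; 4 lists at an unadjusted p under 0.05). Member counts below are over all genes in the fit with 1 probe set per gene. Of the 61 list genes called there, 14 passed in every fit with 1 array left out and 17 in none of them. Of the genes named below, those that passed in none were E2f7, Brca1, Rad50, Suz12, Procr, Gfi1, Ctsg, Cdk6, Cdkn1c, Cdkn1a and Trp53inp1. In those fits between 0 and 1 E2F family, 0 and 2 DNA repair, 3 and 5 lymphoid priming, 7 and 9 neutrophil, 0 and 3 B cell, and 1 and 5 immediate-early members passed. Other probe sets of some list genes named below differed less, down to 0.05 for E2f8, 0.03 for Cenpf, 0.14 for Rad50 and 0.03 for Acvr1b. The same held for genes that fell, where another probe set read 0.11 for Ndn, -0.06 for Ccr9, -0.18 for Igll1, 0.01 for Cd247 and -0.05 for Trp53inp1.

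Mitosis genes were higher as a group. All 42 measured members had higher means in deficient cells, 10 rose past the threshold and 32 did not pass it, with 32 rising when adjusted over the list alone. Bub1, a spindle checkpoint kinase gene, rose from 8.36 ± 0.02 to 9.67 ± 0.10 and Espl1 from 8.35 ± 0.02 to 9.96 ± 0.17. The proliferation marker Mki67 rose from 11.38 ± 0.08 to 12.49 ± 0.06 and the kinetochore gene Cenpf from 7.95 ± 0.06 to 9.29 ± 0.21. The list median was 0.71 (camera adjusted p = 1.45e-23; adjusted p = 0.191 with an estimated correlation). Without control 1 the median was 0.57 and 1 member passed, and without any other array between 2 and 5 passed.

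The list of E2F and DP transcription factors was also higher (median 0.20, camera adjusted p = 0.00697; adjusted p = 0.191 with an estimated correlation). The median was 0.14 without control 1 and 0.33 without control 2. Of its 10 genes, 2 rose: E2f8 from 9.45 ± 0.04 to 10.71 ± 0.12 and E2f7 from 7.39 ± 0.30 to 8.51 ± 0.12. Both encode atypical E2Fs, which repress transcription and lack the domain that binds pocket proteins. The other 8 did not pass, among them E2f3 (difference 0.61, adjusted p = 0.0578) and the partner gene Tfdp1 (0.52, adjusted p = 0.126); 4 rose when adjusted over the list alone.

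DNA replication genes were higher as a list (median 0.33 over 48 genes, camera adjusted p = 1.74e-09; adjusted p = 0.347 with an estimated correlation), although 0 members passed in limma, over all genes or over the list alone. At an unadjusted p under 0.05, 17 were higher. The smallest p-values belonged to Tipin (0.71), Clspn (0.76), Pold1 (0.67) and Cdc7 (0.57), each with an adjusted p of at least 0.0753. Without control 1 the replication list median was 0.14, and without control 2 it was 0.50. Fry did not call the list (adjusted p = 0.140). DNA repair genes were higher as well (median 0.51 over 22 genes, camera adjusted p = 5.53e-09; adjusted p = 0.191 with an estimated correlation): 3 rose, 19 did not pass, and 6 rose when adjusted over the list alone. The 3 were the tumour suppressor genes Brca1 (8.67 ± 0.09 to 9.72 ± 0.19) and Brca2 (9.36 ± 0.27 to 10.36 ± 0.03), which act in homologous recombination, and Rad50 (9.20 ± 0.03 to 10.02 ± 0.13).

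Of 14 chromatin assembly genes, 1 rose, the Polycomb subunit gene Suz12 (9.36 ± 0.04 in controls, difference 0.64), and 13 did not pass, with 9 rising when adjusted over the list alone. Hells, a chromatin remodeller gene, differed by 0.81 (adjusted p = 0.0580). The list median was 0.47 (camera adjusted p = 9.30e-07; adjusted p = 0.191 with an estimated correlation). Ribosome biogenesis genes had a median of 0.35 (camera adjusted p = 1.05e-07; adjusted p = 0.273 with an estimated correlation). All 20 means were higher and 0 members passed in limma, with 11 higher at an unadjusted p under 0.05 and 6 rising when adjusted over the list alone. Polr1b and Nolc1 each differed by 0.59, and Myc by 0.58 (adjusted p = 0.111).

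Genes enriched in long-term haematopoietic stem cells were lower as a list (median -0.84 over 26 genes, camera adjusted p = 2.35e-06; adjusted p = 0.347 with an estimated correlation). 6 members fell, 1 rose and 19 did not pass; adjusted over the list alone, 15 fell and 3 rose. Procr, the endothelial protein C receptor used to mark stem cells, fell from 10.49 ± 0.31 to 8.87 ± 0.31. Ndn, which encodes necdin, fell from 10.51 ± 0.07 to 7.66 ± 0.78, and the lectin gene Clec1a from 6.86 ± 0.62 to 5.04 ± 0.13. Gfi1, a transcriptional repressor, was the member that rose (8.77 ± 0.02 to 9.68 ± 0.17). Without control 1 the list median was -0.49 and 0 members passed in limma, and without control 2 it was -1.26 and 2 fell. Fry did not call this list (adjusted p = 0.108).

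Lymphoid priming genes were lower too (median -0.72, mean -1.48 over 11 genes, camera adjusted p = 7.81e-08; adjusted p = 0.183 with an estimated correlation). 4 fell and 7 did not pass, and 6 fell when adjusted over the list alone. Rag1, a recombinase gene of antigen receptor assembly, fell from 6.74 ± 0.16 to 4.02 ± 0.06. The interleukin 7 receptor gene Il7r fell from 8.46 ± 0.16 to 4.76 ± 0.38, Ccr9 from 5.78 ± 0.25 to 3.43 ± 0.04 and Ltb from 9.87 ± 0.51 to 7.53 ± 0.09. Rag1, Ccr9 and Il7r passed in all 5 fits with 1 array left out. Of the 4, Ltb passed in 4 of those fits. The B cell list was also lower (median -0.74 over 10 genes, camera adjusted p = 1.66e-05; adjusted p = 0.183 with an estimated correlation), with 1 member past the threshold and 9 not passing, and 6 falling when adjusted over the list alone. That member was Igll1, a surrogate light chain gene of B cell precursors (7.61 ± 0.53 to 5.84 ± 0.13). Vpreb1 differed by -3.18 (adjusted p = 0.0686) and Ighm by -3.25 (adjusted p = 0.0707).

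The list fixed as mature granulocyte genes, named without a test of cell stage, had the largest fall of the 24 lists. 11 of 12 measured members fell, over all genes and over the list alone, and Itgam did not pass. Lcn2, which encodes an iron-siderophore-binding granule protein, fell from 12.07 ± 0.40 to 9.34 ± 0.09, and Ngp from 13.84 ± 0.15 to 7.69 ± 0.55. The list median was -4.82 (camera adjusted p = 2.77e-16; adjusted p = 0.183 with an estimated correlation). Granulocyte-monocyte progenitor genes went both ways, and the list was not called (median 0.14 over 14 genes, camera adjusted p = 0.212). 4 rose, 1 fell and 9 did not pass; adjusted over the list alone, 7 rose and 3 fell. The membrane protein gene Ms4a3 (10.83 ± 0.59 to 12.41 ± 0.11) and the granule protease gene Ctsg (13.06 ± 0.20 to 13.88 ± 0.02) rose with Csf2rb, while the lysozyme gene Lyz2 fell from 12.43 ± 0.20 to 10.47 ± 0.09. Without control 2 the progenitor list passed (median 0.35, adjusted p = 0.0474), and without control 1 it did not (median 0.09, adjusted p = 0.425).

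T and NK cell genes were lower (median -0.23, mean -0.66 over 13 genes, camera adjusted p = 0.0130; adjusted p = 0.347 with an estimated correlation). Klrd1, an NK cell receptor gene, fell from 6.43 ± 0.15 to 4.07 ± 0.07 and Cd247, the zeta chain of the T cell receptor, from 5.67 ± 0.44 to 4.24 ± 0.18; 11 members did not pass, and adjusted over the list alone 4 fell and 1 rose. The median was -0.39 without control 1. This list was not called without control 2 (median -0.08, adjusted p = 0.120), the array that read 7.26 for Cd3g where the other 4 read between 3.57 and 3.79. Macrophage and dendritic cell genes were lower (median -0.48 over 13 genes, camera adjusted p = 0.000548; adjusted p = 0.183 with an estimated correlation). Cd74, the invariant chain of MHC class II, fell from 8.70 ± 0.37 to 5.99 ± 0.63; 12 members did not pass, and 6 fell when adjusted over the list alone. The class II genes H2-Aa and H2-Eb1 differed by -2.70 (adjusted p = 0.0881) and -2.12 (adjusted p = 0.104). In the fit over all probe sets, 1 of the 4 for H2-Aa passed as lower, and the 4 differed by -2.89 to -1.2.

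Immediate-early genes, which also answer to cell handling, were lower as a list (median -1.02 over 20 genes, camera adjusted p = 1.20e-10; adjusted p = 0.191 with an estimated correlation). 8 fell and 12 did not pass, and 15 fell when adjusted over the list alone. Without control 1 or without deficient 2, 1 member passed. Fos fell from 12.83 ± 0.07 to 10.92 ± 0.32, Klf4 from 6.78 ± 0.59 to 4.29 ± 0.16, Klf2 by 1.72 on the log2 scale from 6.72 ± 0.14 and the phosphatase gene Dusp1 from 10.69 ± 0.39 to 9.28 ± 0.01.

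The remaining 10 lists were not called by camera. Fry, which does not compare a list with other genes, called some of them. These were glycolysis (fry adjusted p = 0.00902), apoptosis (0.0191), stroma and endothelium (0.0219) and p53 targets (0.0446). Adjusted p-values beside list medians below are from camera. Among 13 CDK inhibitor, D-type cyclin and interphase CDK genes (median -0.06, adjusted p = 0.457), Cdk6, the kinase partner of D-type cyclins, rose from 12.04 ± 0.04 to 13.01 ± 0.04. The inhibitor genes Cdkn1c and Cdkn1a fell, Cdkn1c from 8.27 ± 0.55 to 6.33 ± 0.38 and Cdkn1a from 10.03 ± 0.24 to 9.03 ± 0.20; 10 did not pass, and adjusted over the list alone 1 rose and 2 fell. Of 20 p53 target genes (median -0.07, adjusted p = 0.196), 2 fell, Cdkn1a and Trp53inp1 (10.40 ± 0.17 to 9.50 ± 0.16), and 18 did not pass; adjusted over the list alone, 7 fell and 1 rose. Among 18 apoptosis genes (median -0.10, adjusted p = 0.442) 0 passed in limma, over all genes or over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05; the smallest p belonged to Casp6 (-0.78, adjusted p = 0.0895).

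Erythroid genes (14 measured, median -0.18, adjusted p = 0.442) had 0 calls in limma, over all genes or over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. The list holds 1 dim globin probe set, and 2 probe sets shared by alpha-globin genes, outside the list because they carry several symbols, differed by -3.54 and -3.48 (adjusted p = 0.0341 and 0.0396). Of 15 megakaryocyte genes (median 0.03, adjusted p = 0.301), Itga2b, the platelet integrin CD41, rose from 10.19 ± 0.01 to 11.38 ± 0.19, the same call as over the list alone, and 14 did not pass. Among 10 mast cell, basophil and eosinophil genes (median 0.47, adjusted p = 0.0969), the eosinophil granule gene Prg2 fell from 5.77 ± 0.63 to 3.86 ± 0.08 and 9 did not pass; adjusted over the list alone, 5 rose and 1 fell. Fcer1a, the IgE receptor alpha chain, read 6.99 ± 0.76 and 9.23 ± 1.04 (difference 2.24, adjusted p = 0.127). The list passed without deficient 3 (median 0.70, adjusted p = 0.0243) and in no other fit with 1 array left out, where its median ran from 0.34 without deficient 1 (adjusted p = 0.496) to 0.91 without control 2 (adjusted p = 0.0682). Of 22 niche receptor and adhesion genes (median 0.16, adjusted p = 0.108), 1 rose over all genes and over the list alone, the activin receptor gene Acvr1b (9.50 ± 0.03 to 10.53 ± 0.26), and the list passed without control 1 (median 0.23, adjusted p = 0.0124) but not without control 2 (median 0.05, adjusted p = 0.709).

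Interferon-stimulated genes showed no call in limma among 24 measured, over all genes or over the list alone (median -0.08, camera adjusted p = 0.604), with 1 lower at an unadjusted p under 0.05; Irf9 differed by -0.50 (adjusted p = 0.102). Glycolysis genes likewise had 0 calls among 11 (median 0.10, adjusted p = 0.196; at an unadjusted p under 0.05, 2 were higher and 1 lower), with 0.41 for Hk1. Stromal and endothelial genes had 0 calls among 8 over all genes (median -0.03, adjusted p = 0.572; 1 higher and 2 lower at an unadjusted p under 0.05, and the same counts over the list alone), with -0.72 for Kdr.

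**Figure D3:**
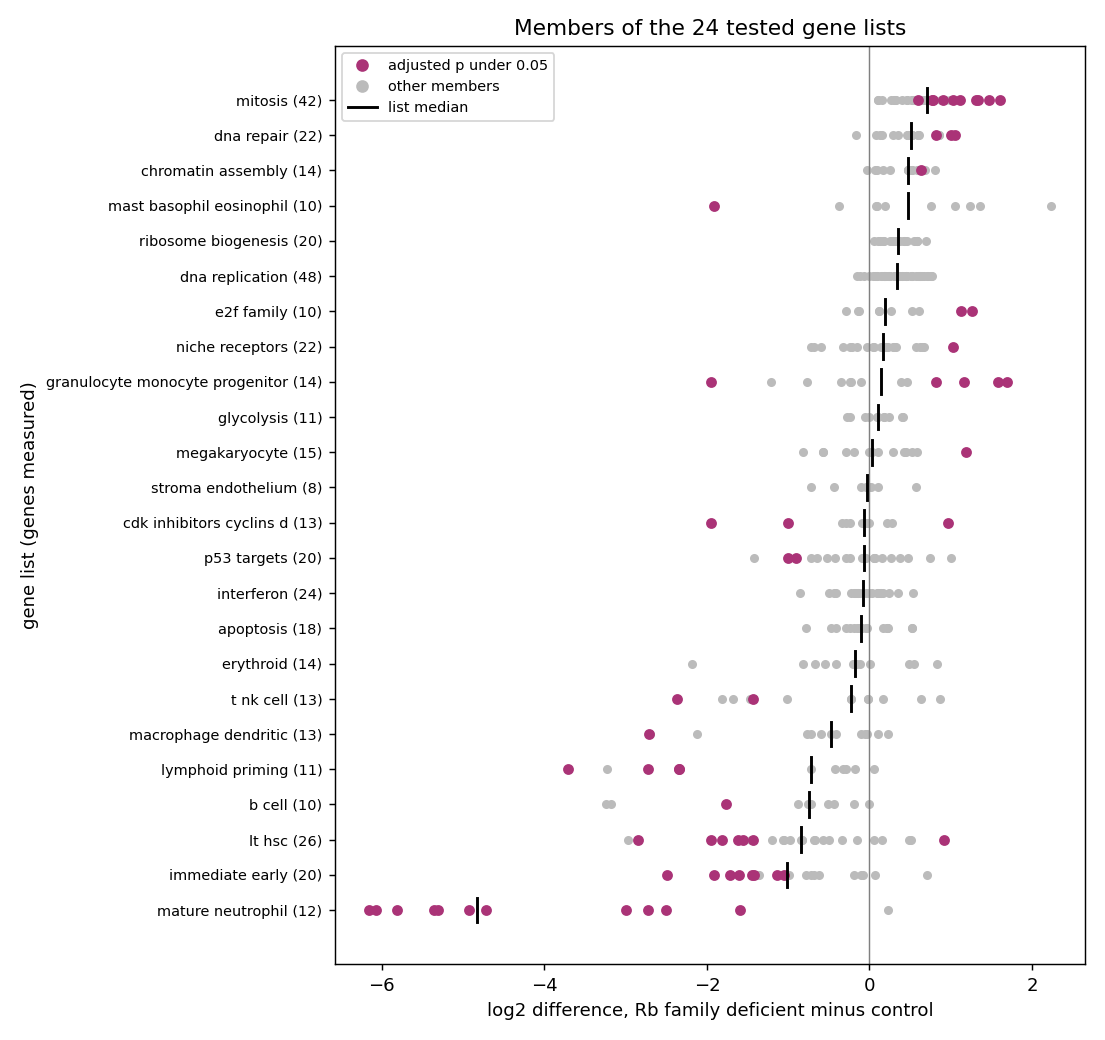
Log2 difference, Rb family deficient minus control, of each measured member of the 24 tested gene lists, with members at adjusted p under 0.05 (limma, 1 probe set per gene) in purple, other members in grey and the list median as a black bar. Medians run from -4.82 for the mature neutrophil list to 0.71 for the mitosis list, whose 42 members all lie above 0.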

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

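The Xist and poly-A covariates were chosen after seeing the data. Quantile normalization again, cyclic loess, median centring, leaving out dim or _x_at and _s_at probe sets, array weights, a robust prior and a 1.5-fold minimum kept the counts within 1.5 times of 74 higher and 147 lower probe sets. An intensity trend gave 141 and 260, of which 63 and 138 were among those, and adjusted p under 0.1 gave 451 and 497. The Xist covariate gave 31 higher (112 lower), and the poly-A spike covariate 16 and 51. With 1 array left out, the counts ranged from 2 to 5 higher and from 21 to 73 lower, and fewer arrays were fitted; where a group kept 1 array, it was assumed to vary like the other group. The replicate number as a block gave 0 higher and 15 lower in limma (unadjusted p under 0.05: 2923 and 2495). No other array shares the number of deficient 3, so the block in effect sets that array aside. Its differences are those of the fit without deficient 3 (Rbl1 -3.049 in both). Samples with the same number did not deviate together (correlations of deviations -0.053 and -0.018), so the numbers were not taken as pairs. Rbl1 (-3.04) passed the threshold with median centring (-3.02), with dim probe sets left out (-3.04, fewer tests), with an intensity trend (-3.04), at adjusted p under 0.1 (-3.04) and with the Xist covariate (-3.13); its adjusted p ranged from 0.0210 to 0.142 over all alternatives, and its difference from -3.62 to -2.45 with 1 array left out. Rb1 and Rbl2 passed in none. An estimated correlation in camera gave 0 higher and 0 lower lists; the estimates ran from -0.133 to 0.486 over the 24 lists. Otherwise 6 to 7 lists were higher and 6 to 7 lower in camera; fry gave 6 and 9, of which 5 and 6 were among those called by camera. No called result reversed. Medians of 4 lists that were not called changed sign: p53 targets (0.001 with the block and without deficient 3), megakaryocyte (-0.013 without control 1), interferon (0.014 without control 1) and stroma and endothelium (0.020 with the block and without deficient 3, 0.023 without control 2). Except where an alternative's construction is named, the cause was not tested. Dim probe sets set a further limit, since RMA compresses differences near background.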

Other observations

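Of the tests in this part, those on several mature cell types, on other splits of the arrays and on control 1 for the mitosis genes were chosen after the results were seen, and so were the genes named here that lie outside the rule for named genes. Deficient cells had more of several transcripts for chromatin regulators outside the fixed lists: Setd1b rose by 1.28 on the log2 scale (SE 0.22), the SWI/SNF subunit gene Arid1a by 1.04 (SE 0.13) and Kmt2e by 0.78 (SE 0.11), beside Kmt2d. A hypothesis that genes of the same complexes may rise as a class was tested on 31 other members of the COMPASS and SWI/SNF complexes. Their median was 0.235 (interquartile range 0.418), between the bounds set in advance for and against, so the hypothesis stays open. In limma 0 of them passed, while 11 were higher and 0 lower at an unadjusted p under 0.05 (camera p = 5.43e-06; p = 0.0139 with an estimated correlation).

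The stem cell genes Cdkn1c and Ndn, both imprinted, fell in deficient cells. A hypothesis that imprinted genes may fall as a class was tested on 10 others above the array median in a group, whose median was -0.218. That lay between the bounds set in advance for and against, close to the bound against. Grb10 (-1.12, adjusted p = 0.108), Igf2r (-0.99, adjusted p = 0.101) and Sgce (-0.84, adjusted p = 0.131) had the smallest p-values and missed the threshold in limma. The rest ran from -0.227 (Dlk1) to 0.239 (Gatm), and the hypothesis stays open.

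Granule and immunoglobulin transcripts were far lower in the deficient cells. Less RNA from mature cells of several types in the deficient sorts may contribute, although the lineage-negative gate would remove such cells. It was tested on the B cell, T and NK cell, and macrophage and dendritic cell lists, whose medians over all measured members were -0.738, -0.229 and -0.478, so not all lay below the bound of -0.5 and the explanation stays open. This is the last of 3 forms of the test, each chosen after earlier results were seen. Another form kept only members above the array median in controls, which favours falls, and gave -1.77, -1.02 and -0.718. The form over all members leans the other way, since dim members such as Ncr1, Il2rb, Pax5 and C1qb could hardly fall. Igha and Jchain are in none of these lists, so no form of the test can tell where the immunoglobulin transcripts that fell most came from. The earliest compared the neutrophil list with the erythroid, megakaryocyte, and mast cell, basophil and eosinophil lists, whose medians over such members were -0.284, 0.10 and 0.908 against -4.93. Of those members, 10 of 10, 13 of 13 and 7 of 8 lay above the array median in deficient cells too, as did 9 of 11 neutrophil, 5 of 5 B cell, 5 of 11 T and NK cell and 7 of 9 macrophage and dendritic cell members, so a small lost share could be hidden and no form excludes the explanation. The 2 probe sets shared by alpha-globin genes fell by 3.54 and 3.48 on the log2 scale (adjusted p = 0.0341 and 0.0396). Mature granulocytes alone were tested on 19 further neutrophil genes above the array median in controls. Their median of -0.705, the same over all 23 measured, lay between the bounds for and against: G0s2 fell by 2.13 (adjusted p = 0.00201) and the abundant Lyz1 by 1.21 (adjusted p = 0.00841), while Hp differed by 0.13 and Clec4d by less than its SE of 0.12. Lost transcription in the KLS cells themselves, through the genotype, stays open and was not tested. The real split called 221 probe sets, 1 of 10 splits of the 5 arrays did so, and the highest of the others called 2; the splits are too few for a share under 0.05.

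Immediate-early genes were lower in deficient cells as a list (not called with an estimated correlation, adjusted p = 0.191). Stress of the cells in handling, stronger in the control sorts, may contribute, and was tested on 15 heat shock genes other than Hspa1b. Their median was -0.282, between the bounds set in advance for and against, so it cannot tell handling apart from genotype. Members went both ways: Hspa1a fell by 4.28 (adjusted p = 0.0356) and Dnajb1 by 0.90 (adjusted p = 0.0360), while Hspa4 differed by 0.58 (adjusted p = 0.151). A single control array was not the cause of the list's fall, since the higher of the medians without control 1 or control 2 was -0.832. RNA quality stays open too: on all deficient arrays the beta-actin 3' minus 5' signal was higher and 18S ribosomal RNA lower than on both controls (exact permutation p = 0.1 each). The genotype stays open and was not tested apart from handling.

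Mitosis genes were higher in deficient cells as a list (not called with an estimated correlation, adjusted p = 0.191). A slower cycling control 1 alone was tested as the cause: without that array the list median was 0.573, against 0.711 with it, so control 1 raised the value and did not make it. The genotype, in which pocket proteins no longer restrain the cell cycle, and a different mix of cell types within the KLS sort both stay open and were not told apart.

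Levels of sex-linked genes differed between arrays of the same group. Xist read 6.12 and 10.67 on controls 1 and 2, and 5.09, 12.45 and 5.51 on deficient arrays 1, 2 and 3. The Y-linked Eif2s3y read 9.81 and 9.82 on the controls, and 10.21, 3.50 and 10.37 on the deficient arrays. Deficient 2 thus came from a different source than deficient 1 and 3. Its levels read as female, with Kdm5d at 3.25 and Uty at 3.85 on their brightest probe sets. Deficient 1, deficient 3 and control 1 read as male. Xist set the 2 controls apart as well. Control 2 had both Xist (9.31 on another probe set) and Y-linked signal (Kdm5d 6.70), so its RNA does not read as that of a single sex. The cause was not tested. The spread within the groups is therefore not wholly technical. Gzma read 4.45 on control 1 and 6.70 on control 2.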
